A study of Mus musculus with 6 samples.

How the data were processed

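Total RNA was taken from ventral dermis of 3 mutant mice, with activated beta-catenin in dermal fibroblasts, and 3 control littermates, on a mixed CD1 and C57BL/6 background, and made into stranded paired-end libraries (TruSeq Stranded Total RNA), per the labels' protocols. The labels name separate mice, so p-values measure the spread between mice and their libraries. Average insert sizes in the labels ran from 362 to 375 bases. GSNAP (an aligner), HTSeq (a read counter) and genome build mm10 are named, per the submitters' processing notes, and their versions, the annotation and the counting options are not given in the sources used here.

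The deposited table holds 1 FPKM value (fragments assigned to a gene, divided by its length and by the library's depth) per gene and library, as the authors computed it. Which fragments make up the depth and which gene length was used are not given in the sources used here. FPKM sums differed between libraries: 220696, 192880 and 235396 in controls 1 to 3 and 281766, 203446 and 233457 in mutants 1 to 3. Such a sum depends on the most abundant genes as well as on an offset shared by all genes of a library. Median-of-ratios factors, which follow the middle gene, were 1.02, 0.878 and 1.00 in controls 1 to 3. In mutants 1 to 3 they were 1.19, 0.916 and 1.05. Control 3 thus had a higher sum than control 1 but no higher factor. Among the alternatives were 3 other scalings. The table's gene symbols were matched by name, or by a single synonym in the RefSeq gene table for mouse, to GENCODE release M21 (GRCm38), which gave a location for 23003 of 23412 genes. Older symbols such as Nov, Wisp2, Sfpi1 and Leprel4 are printed as deposited.

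Within a gene, FPKM values were whole multiples of a common step, and the steps gave each library's relative depth and reads per gene. A whole-number solution was found for 23412 of 23412 genes (100%), within the rounding of each value and a relative tolerance of 3e-09. This count includes 1820 genes at 0 in all libraries and genes seen in a single library, which were set to a single read. For those genes nothing could be checked. The smallest solution was taken, so a gene whose reads share a common divisor would come out too low. On a simulated table, 98.5% of 14880 genes with 50 or more reads were given back exactly. Gene reads were 9675359, 7799565 and 8931815 in controls 1 to 3 and 13478910, 11839144 and 12562416 in mutants 1 to 3. The depth that divides FPKM, relative to control 1, was 0.932 and 0.878 in controls 2 and 3 and 1.15, 1.25 and 1.25 in mutants 1 to 3. A single gene, the ribosomal RNA precursor Rn45s, took 5.28%, 3.03% and 3.71% of gene reads in the controls and 1.96%, 8.10% and 2.65% in the mutants. Recovered reads were used for depth, for composition and for an added limma-voom test, never for the main result. With mean FPKM 1 as the floor, low genes rest on few reads, such as 15 to 25 per control library for Cd52.

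Values were compared as log2(FPKM + 1). This scale understates the change of low genes. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, 12560 in all, of which 265 have small RNA symbols. The test was limma (version 3.58.1, R 4.3.3) with an intensity trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had no covariate or block, and the prior had 5.44 degrees of freedom. An exact permutation test of a single gene with 3 against 3 libraries cannot give a p below 0.1, so all p-values rest on the model's pooled variance. Pairs of libraries of the same group differed by more than counting noise (chi-square per degree of freedom from 15.6 to 79.4). None was therefore the same library sequenced again. That each came from its own mouse rests on the labels.

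Of 38 gene lists, 33 with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over lists. Camera with a correlation estimated from the 6 libraries and fry were alternatives. The lists held 779 gene entries, of which 771 were found in the table, and some genes are in more than 1 list. They cover Wnt targets, Wnt ligands and receptors, matrix groups, TGF-beta, contractile, adipocyte, cytokine, interferon, stress, unfolded protein, proliferation and lipid synthesis genes, and markers of the cell types that dissected dermis can hold. T cell, B cell, neutrophil and red blood cell lists had too few tested members, and a list of Xist and Y-linked genes served only to check library sex. For each list, members past the threshold were counted over all genes and with p adjusted over the list alone. Most marker genes of one cell type are also expressed elsewhere in skin, so lists describe RNA levels and not cell numbers.

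The named genes followed a rule: Ctnnb1, Hoxb6, Axin2 and Lef1 in any case; the 10 largest rises and falls among called genes with separate groups, filled up by smallest p where fewer passed and without small RNA genes; and up to 4 members of each list described. The samples' groups, the tests, the lists, this rule and the first group of other settings below were chosen before the data were examined. That group held another pseudocount (0.1), no filter and a stricter filter (mean FPKM 5), median-of-ratios, quantile and tissue-gene-free scaling, limma without trend or with a robust prior, sample weights, a replicate block, small RNA genes left out, a threshold of 0.1 and each of the 6 libraries left out. The voom test, library sex as a covariate, the fit without both Xist-high controls and the fit without X and Y genes were added after the data were seen.

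The analysis was tested on simulated data for 3 mutant against 3 control libraries with 12628 genes tested, 200 of them changed. Genes changed 1.5-fold were called in 10.4% of cases, 2-fold in 74.2% and 4-fold in 95.2%. There were 14 false calls, 7 of them small RNA genes. With no change simulated, 1 gene and 0 lists were called. The simulated libraries varied more evenly from gene to gene than the real ones (prior degrees of freedom 10.5 against 5.44), and each gene was drawn independently, so the 0 lists says nothing of lists whose genes vary together between mice.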

Results

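RNA from the ventral dermis of 6 mice was sequenced: 3 carried an activated form of beta-catenin in part of their dermal fibroblasts and 3 were littermate controls. Beta-catenin, encoded by Ctnnb1, carries the canonical Wnt signal to the nucleus. Loss of its exon 3, which holds the phosphorylation sites that mark the protein for degradation, stabilises it. In the mutant mice a tamoxifen-inducible Cre recombinase under Hoxb6 control removed that exon. The controls carried the Cre and a yellow fluorescent reporter but no floxed Ctnnb1 allele. All mice received tamoxifen through their mother on embryonic day 16.5, and skin was taken at 3 weeks of age. The epidermis was separated after trypsin, and dermis of this kind can still hold hair follicles, fat, vessels, nerve and immune cells. The comparison asks which genes differ in dermis in which fibroblasts have carried active beta-catenin since late embryonic life, a state the study links in its title to skin fibrosis.

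The table gave FPKM values for 23412 genes, and 12560 had a mean of at least 1 FPKM over the 6 libraries and were tested. Reads assigned to genes came to 9675359, 7799565 and 8931815 in controls 1 to 3 and to 13478910, 11839144 and 12562416 in mutants 1 to 3. Every pair of libraries had a Pearson correlation across genes between 0.946 and 0.984 on the log2(FPKM + 1) scale. The sexes were not balanced. Controls 1 and 2 had 55.5 and 66.2 FPKM of Xist, the RNA of the inactive X chromosome, and at most 1 read in each of 4 Y-linked genes. Control 3 and all 3 mutants expressed the Y-linked genes. Mutant 2 also had 6.47 FPKM of Xist, from 2475 reads.

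The engineered gene showed no difference at the level of the whole gene. Ctnnb1 (chromosome 9, 120929216 to 120960507, GRCm38) stood at 182 ± 19.4 FPKM in controls and 165 ± 28.7 in mutants (mean ± SD, n = 3 each), a log2 difference of -0.15 (95% interval -0.67 to 0.37; adjusted p = 0.895). Loss of a single exon in some of the cells cannot be read from a value for the whole gene, so this checks neither the genotype nor the labels. Hoxb6 (chromosome 11, 96292476 to 96301569), the locus that drives the Cre, was at 2.47 ± 1.02 FPKM in controls and 2.21 ± 0.21 in mutants (log2 difference -0.08, adjusted p = 0.944).

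In activated beta-catenin dermis 18 genes rose and 0 fell (limma with Benjamini-Hochberg adjustment). In each of the 18, all 3 mutants lay above all 3 controls. The largest rise was in Nov, also called Ccn3, which encodes a secreted matricellular protein (chromosome 15, 54745702 to 54754039). It went from 2.2 ± 1.03 FPKM in controls to 20.7 ± 9.09 in mutants, a log2 rise of 2.71 (SE 0.34, adjusted p = 0.0252), with 45 to 133 reads per control library and 531 to 1293 per mutant library. Its relative Wisp2 (chromosome 2, 163820861 to 163833146), of the same CCN family, rose by 1.70 (SE 0.25, adjusted p = 0.0442). Igfbp2, which binds insulin-like growth factors (chromosome 1, 72824503 to 72852474), rose from 9.63 ± 2.50 to 51.5 ± 18.8 FPKM, or by 2.27 (SE 0.27, adjusted p = 0.0252). The secreted protein gene C1qtnf3 (chromosome 15, 10952332 to 10980150) rose by 2.14 (SE 0.27) and the cytochrome P450 gene Cyp2f2 (chromosome 7, 27119909 to 27133660) by 2.25 (SE 0.28). Tmem132c (chromosome 5, 127241808 to 127565793), a membrane protein gene, rose by 1.60 (SE 0.19), and the glutaminyl cyclase gene Qpct (chromosome 17, 79051906 to 79090378) by 1.59 (SE 0.23).

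Cd52, a surface glycoprotein of leukocytes (chromosome 4, 134082448 to 134095082), rose from 2.31 ± 0.53 to 8.0 ± 1.19 FPKM, a log2 rise of 1.45 (SE 0.15, adjusted p = 0.0242). The Fc receptor gamma chain gene Fcer1g (chromosome 1, 171229572 to 171234365) rose from 3.70 ± 0.47 to 10.6 ± 0.77 FPKM, by 1.30 (SE 0.13, adjusted p = 0.0242). Coro1a (chromosome 7, 126699773 to 126707787), an actin regulator of leukocytes, rose by 1.35 (SE 0.20, adjusted p = 0.0442). The rest of the 18 fell outside the rule for named genes and were picked after their values were seen. They included Ptprc, the common leukocyte antigen, Sfpi1, the myeloid transcription factor known as Spi1, and Cd48, Lilrb4, H2-DMa and Entpd1, with log2 rises from 0.90 for Lilrb4 to 1.26 for Entpd1. The other 2 encode adhesion proteins: Cdh4 with a log2 rise of 1.13 and Lsamp with 1.21.

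**Figure D1:**
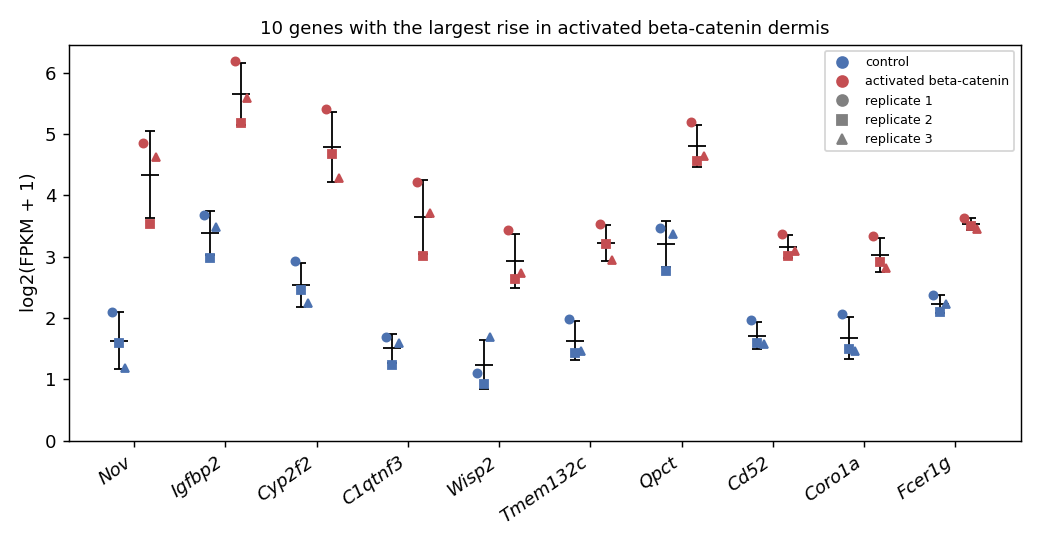
Expression of the 10 genes with the largest rise, as log2(FPKM + 1) on the vertical axis, in 3 control (blue) and 3 activated beta-catenin (red) libraries; marker shape gives the replicate number, and the black dash and bars give the mean and SD. In each gene the 3 mutant libraries lie above the 3 control libraries, and Nov has the largest difference, 2.71.

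The number of called genes depended on single libraries and on the settings. Genes called higher numbered 29, 11 and 189 without controls 1, 2 and 3, and 8, 3 and 49 without mutants 1, 2 and 3. Genes called lower numbered 0, 0 and 4 without these controls and 2, 0 and 3 without these mutants. At an unadjusted p under 0.05, 1323 genes were higher and 94 lower, and this split depended on the scaling: 93.4% of such genes were higher in the deposited values and 63.1%, 54.6% and 49.4% after median-of-ratios scaling, quantile normalization and rescaling without muscle, hair, keratinocyte, blood and mitochondrial genes. The median of all tested genes was 0.09 as deposited and -0.01, -0.03 and -0.05 under these scalings, so a list is best read against that median. Genes whose groups did not overlap numbered 1627 upward and 333 downward, 15.6% of those tested where chance gives 10%.

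No gene fell past the threshold (0 with limma on FPKM, 94 at an unadjusted p under 0.05; limma-voom on recovered reads also called 0). With small RNA genes set aside, the 10 with the smallest p had adjusted p from 0.155 to 0.227. Some small RNA genes had lower ones, the lowest being 0.0803 for Mir150. Among the 10 were Krt74, listed in GENCODE as a transcribed pseudogene in mouse, with a log2 difference of -0.54, the transcription factor gene Tfap2a (-0.44), Ccser1 (-0.56), Nav2 (-0.48), the epithelial serpin Serpinb13 (-0.48), the ghrelin gene Ghrl (-0.47) and the kinase gene Nek5 (-0.54). The remaining 3 were 4933401H06Rik (-0.50), Gm6525 (-0.56) and 4930579G18Rik (-0.42).

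Genes of the extracellular matrix had log2 medians of 0.44 to 0.81 in the mutant dermis against 0.09 for all tested genes, and their lists passed with camera's preset correlation and not with an estimated one. Of 25 tested genes for collagen processing and cross-linking, all 25 were above 0, with a median of 0.81 (camera adjusted p = 4.61e-12, adjusted p = 0.517 with an estimated correlation). None of the 25 was called over all genes, and 22 passed when adjusted over the list alone. Loxl2, a lysyl oxidase that cross-links collagen, was at 11.6 ± 3.58 FPKM in controls and 23.8 ± 5.33 in mutants, and Adamts2, which trims procollagen, at 17.3 ± 6.42 and 38.5 ± 10.9. Loxl4 had a log2 difference of 0.81 and Leprel4 of 0.88. The 40 genes of elastic fibres and matrix glycoproteins had a median of 0.62 (camera adjusted p = 1.54e-11, adjusted p = 0.517 with an estimated correlation), with 0 called over all genes and 17 adjusted over the list alone. Thbs2, a thrombospondin, was at 11.9 ± 2.38 and 36.1 ± 11.1 FPKM (adjusted p = 0.0505) and Thbs4 at 6.18 ± 1.87 and 18.8 ± 5.58 (adjusted p = 0.0647). The fibulin genes Fbln1 and Fbln5 had log2 differences of 0.80 and 0.77. Of 15 proteoglycan genes, all 15 were above 0, with a median of 0.54 (camera adjusted p = 2.38e-10, adjusted p = 0.517 with an estimated correlation), 0 called over all genes and 12 adjusted over the list alone. The collagen-binding Lum was at 55.0 ± 16.5 FPKM in controls and 156 ± 45.4 in mutants (adjusted p = 0.0845), and Aspn at 34.8 ± 10.4 and 89.9 ± 19.5 (adjusted p = 0.0803). Vcan and Spock2 had differences of 0.70 and 0.67. Against the control mean the median of the processing list was 0.08, -0.49 and 0.37 in controls 1 to 3 and 1.04, 0.65 and 0.56 in mutants 1 to 3, so the lowest values were those of the Xist-high controls 1 and 2. Control 2 was lowest and mutant 1 highest in the glycoprotein and proteoglycan lists too. On the main axis of variation between libraries (first principal component, 51.0% of variance) control 2 stood at -34.9 and mutant 1 at 33.9. The other libraries lay between -4.74 and 8.45. The values were not rescaled, and control 2 and mutant 1 also had the lowest and highest median-of-ratios factors, 0.878 and 1.19. A library-wide offset is thus not set apart from tissue differences on this axis. After median-of-ratios scaling the processing and glycoprotein medians were 0.73 and 0.51, against -0.01 for all genes. With library sex as a covariate, which leaves the mutants against control 3 alone, the processing median was 0.29 and the glycoprotein median 0.38. Without control 2 they were 0.53 and 0.37. The glycoprotein median was 0.41 without mutant 1.

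The collagens themselves had a median of 0.50 over 23 genes, of which 22 were above 0 and 9 had separate groups (camera adjusted p = 2.34e-07; adjusted p = 0.517 with an estimated correlation). No collagen was called over all genes, and 1 passed adjusted over the list alone: Col7a1, of the anchoring fibrils, at 4.76 ± 0.91 FPKM in controls and 10.7 ± 1.60 in mutants (adjusted p = 0.0549). Col6a1 stood at 65.6 ± 24.0 and 137 ± 39.9 FPKM, Col6a2 at 64.1 ± 30.0 and 129 ± 29.5, and Col5a2 at 69.7 ± 28.3 and 137 ± 37.8, with adjusted p from 0.202 to 0.242. The main fibrillar collagens of dermis, picked after their values were seen, varied widely among the controls. Col1a1 was at 1646, 852 and 4494 FPKM in controls 1 to 3 and at 3927, 3318 and 3180 in mutants 1 to 3, so control 3 exceeded every mutant (log2 difference 0.91, adjusted p = 0.682). Col1a2 was at 1323, 705 and 2817 in controls and 3754, 2608 and 2572 in mutants (adjusted p = 0.523). Col3a1 was at 1690, 894 and 2723 in controls and 4815, 2888 and 3033 in mutants, where every mutant lay above every control (adjusted p = 0.480). With library sex as a covariate the collagen list's median was 0.30 (camera adjusted p = 0.0201). The list took 4.97%, 3.12% and 9.38% of gene reads in controls 1 to 3 and 10.6%, 9.18% and 8.63% in mutants 1 to 3.

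**Figure D2:**
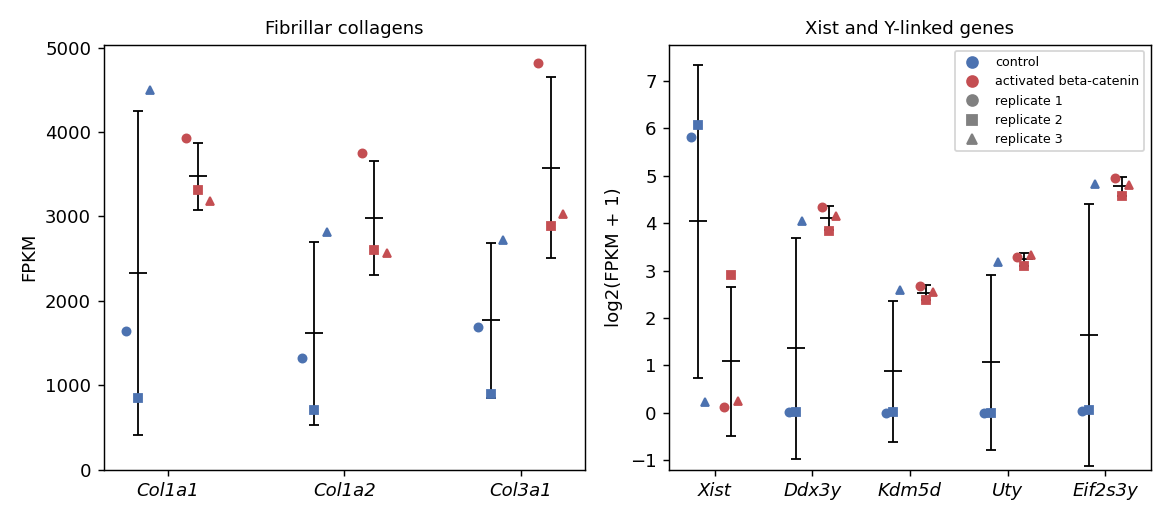
Left, FPKM of Col1a1, Col1a2 and Col3a1, and right, log2(FPKM + 1) of Xist and 4 Y-linked genes, in 3 control (blue) and 3 activated beta-catenin (red) libraries; marker shape gives the replicate number, and the dash and bars give the mean and SD. Control 3 has the highest Col1a1 (4494 FPKM) and shares the Y-linked signal with the mutants, and controls 1 and 2 have high Xist.

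The lists of dermal fibroblast and matrix turnover genes also passed at the preset correlation only. The fibroblast list had 21 tested genes with a median of 0.46 (camera adjusted p = 8.56e-07, adjusted p = 0.517 with an estimated correlation), 0 called over all genes and 11 adjusted over the list alone. S100a4, long used as a fibroblast marker, was at 21.9 ± 6.56 FPKM in controls and 59.0 ± 11.8 in mutants (adjusted p = 0.0647), Twist2, a dermal transcription factor, at 3.16 ± 1.06 and 7.34 ± 1.20 (adjusted p = 0.0845), and Thy1 at 17.3 ± 3.51 and 32.8 ± 6.47 (adjusted p = 0.119). The 25 matrix proteases and inhibitors had a median of 0.44 (camera adjusted p = 2.95e-07, adjusted p = 0.517 with an estimated correlation), with 0 called over all genes and 7 adjusted over the list alone. The collagen-degrading cathepsin gene Ctsk was at 26.1 ± 8.04 and 61.3 ± 16.4 FPKM, and the metalloproteinase genes Mmp27, Mmp16 and Mmp19 had log2 differences of 0.73, 0.65 and 0.81. With library sex as a covariate the protease median was 0.26.

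Transforming growth factor beta genes and contractile genes had smaller list medians than the matrix lists above. The difference between lists was not tested. The TGF-beta list of 24 genes had a median of 0.19 (camera adjusted p = 0.0372, adjusted p = 0.773 with an estimated correlation). In it 1 gene, Nov, was called over all genes and 6 passed adjusted over the list alone. Tgfbi, a TGF-beta-induced matrix protein, was at 26.9 ± 7.17 FPKM in controls and 59.8 ± 19.1 in mutants, Tgfbr2, a receptor, at 17.2 ± 3.42 and 29.3 ± 5.30, and Snai1 at 0.679 ± 0.270 and 1.42 ± 0.031. The list's camera adjusted p was 0.10 without control 1, 0.203 without mutant 2, 0.0507 after median-of-ratios scaling and 0.253 with the mean FPKM 5 filter. Its median was 0.09 with library sex as a covariate (camera adjusted p = 0.273), and without both Xist-high controls the adjusted p was 0.172. The 17 myofibroblast and smooth muscle contractile genes had a median of 0.27 and did not pass (camera adjusted p = 0.121), with 0 called over all genes and 1, Cdh11, adjusted over the list alone. Cdh11, a cadherin of mesenchyme, was at 9.92 ± 1.74 and 16.2 ± 2.2 FPKM (adjusted p = 0.141), while Cnn1, Mylk and Myh11 had differences of 0.49, 0.27 and 0.34 with adjusted p from 0.562 to 0.592. Without control 1 the contractile list passed (camera adjusted p = 0.00669) with a median of 0.41. Its median was 0.10 without control 2 and 0.12 without mutant 1.

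With the mean FPKM 1 filter, immune cell markers had the largest list medians. All 20 tested macrophage and monocyte genes were higher, and in 18 the groups did not overlap. Their median was 1.07 (camera adjusted p = 2.30e-21, adjusted p = 0.517 with an estimated correlation). Over all genes 1 was called, Fcer1g, and all 20 passed adjusted over the list alone. The adaptor gene Tyrobp was at 7.99 ± 2.02 FPKM in controls and 24.0 ± 7.82 in mutants (adjusted p = 0.0647), the Fc receptor gene Fcgr3 at 4.76 ± 0.86 and 11.9 ± 3.52 (adjusted p = 0.0720) and the integrin gene Itgam at 1.5 ± 0.23 and 3.45 ± 0.66 (adjusted p = 0.0744). These genes took 0.0674%, 0.0532% and 0.0777% of gene reads in controls 1 to 3 and 0.169%, 0.122% and 0.119% in mutants 1 to 3. With library sex as a covariate the median was 0.68 (camera adjusted p = 1.02e-17). With no filter on low FPKM the medians of the next 2 lists were smaller, 0.63 for dendritic and 0.39 for mast cell genes. Both were then below the 0.80 of collagen processing genes. The 8 dendritic and Langerhans cell genes had a median of 0.90 (camera adjusted p = 3.08e-04, adjusted p = 0.517 with an estimated correlation), with 0 called over all genes and 5 adjusted over the list alone. The class II genes Cd74, H2-Aa and H2-Ab1 had log2 differences of 1.53, 1.42 and 1.37, and Cd209a of 1.0. The 6 mast cell genes had a median of 1.06 (camera adjusted p = 4.14e-05, adjusted p = 0.517 with an estimated correlation), with 0 called over all genes and 4 adjusted over the list alone: the proteases Cpa3 (4.75 ± 2.74 and 15.7 ± 5.08 FPKM), Cma1 (3.70 ± 0.88 and 10.9 ± 4.63), Mcpt4 (4.70 ± 1.94 and 15.5 ± 7.35) and Tpsb2 (1.92 ± 0.54 and 4.2 ± 0.92).

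The lists of inflammatory cytokines and chemokines (13 genes, median 0.49, camera adjusted p = 0.00130) and of interferon response genes (15 genes, median 0.32, camera adjusted p = 0.00368) passed at the preset correlation. Neither had a member called over all genes or adjusted over the list alone. With an estimated correlation the cytokine list had an adjusted p = 0.517 and the interferon list an adjusted p = 0.696. Without control 1 their camera adjusted p was 0.0930 and 0.0713, and without mutant 3 that of the interferon list was 0.263. Against the control mean the interferon median was -0.08, -0.10 and 0.19 in controls 1 to 3. It was 0.44, -0.14 and 0.84 in mutants 1 to 3. Neither list passed with library sex as a covariate, where the medians were 0.23 and 0.22 (camera adjusted p = 0.0653 and 0.161), or without both Xist-high controls (0.0688 and 0.124). With the mean FPKM 5 filter the cytokine list had an adjusted p = 0.0910. T cell, B cell, neutrophil and red blood cell lists had too few tested genes for a test. The T cell gene Cd3g lay between 0.458 and 1.95 FPKM in controls and between 1.47 and 2.29 in mutants. The neutrophil gene S100a9 was at 7.78 FPKM in mutant 2 and at most 1.06 in the other 5 libraries. The haemoglobin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2, near-identical copies that share reads, were listed at 0 in all 6 libraries, while the red blood cell gene Alas2 was between 2.43 and 4.11 FPKM.

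The adipocyte and lymphatic endothelial lists passed at the preset correlation only. The 27 adipocyte genes had a median of 0.46 (camera adjusted p = 9.13e-08, adjusted p = 0.517 with an estimated correlation), with 0 called over all genes and 10 adjusted over the list alone. Cfd, which encodes adipsin, was at 26.5 ± 9.53 FPKM in controls and 112 ± 52.1 in mutants (adjusted p = 0.0803), Adig at 1.15 ± 0.21 and 4.14 ± 1.61 (adjusted p = 0.0803), and Plin1, which coats lipid droplets, at 4.45 ± 1.36 and 8.84 ± 2.27 (adjusted p = 0.138). The groups overlapped for Retn (log2 difference 0.90). Without mutant 1 the adipocyte median was 0.26 (camera adjusted p = 9.04e-07). The 5 lymphatic endothelial genes had a median of 0.53 (camera adjusted p = 5.42e-05, adjusted p = 0.517 with an estimated correlation), with 0 called over all genes and 4 adjusted over the list alone. Lyve1 was at 3.36 ± 0.47 and 8.14 ± 2.27 FPKM, Mmrn1 at 3.41 ± 1.11 and 7.02 ± 0.43, Flt4 at 1.04 ± 0.33 and 1.92 ± 0.24 and Reln at 1.47 ± 0.21 and 2.16 ± 0.33. The 8 pericyte genes had a median of 0.35 (camera adjusted p = 0.0321, adjusted p = 0.696 with an estimated correlation), with 0 called over all genes and 3 adjusted over the list alone, and did not pass without mutant 2 (camera adjusted p = 0.192). Their median was 0.18 with library sex as a covariate (camera adjusted p = 0.224), and they missed the threshold without both Xist-high controls (0.111), with no filter (0.0571) and with the mean FPKM 5 filter (0.0556). The 15 genes of endothelium at large had a median of 0.22 and did not pass (camera adjusted p = 0.0763), with 0 called over all genes and 1 adjusted over the list alone. They passed without control 3 (camera adjusted p = 0.0497), without mutant 3 (0.0389) and with no filter (0.00938). Without control 2 the pericyte and endothelial medians were 0.20 and 0.14 (camera adjusted p = 0.0210 and 0.166).

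Hair shaft and inner root sheath genes lay lower in the mutant libraries as a group, with the lowest values in mutant 2. All 33 tested genes were below 0, with a median of -0.47 (camera adjusted p = 1.58e-19, adjusted p = 0.517 with an estimated correlation). None was called over all genes or adjusted over the list alone, and in 3 the groups did not overlap. Hoxc13, which controls hair keratins, was at 26.7 ± 1.79 FPKM in controls and 20.8 ± 3.69 in mutants (adjusted p = 0.469), Gata3, of the inner root sheath, at 26.7 ± 1.34 and 21.6 ± 2.93, Foxn1 at 15.6 ± 3.17 and 11.2 ± 3.40, and Krtap3-2 at 83.4 ± 21.6 and 48.5 ± 22.9. Against the control mean the list median was -0.21, 0.02 and 0.22 in controls 1 to 3 and -0.03, -1.26 and -0.22 in mutants 1 to 3, so mutants 1 and 3 lay within or at the edge of the control range. Relative to the median of all genes the list median was -0.55, and -0.31 without mutant 2, where the list still passed (camera adjusted p = 4.19e-12). The list took 4.19%, 5.92% and 4.81% of gene reads in controls 1 to 3 and 3.88%, 2.2% and 3.94% in mutants 1 to 3. Melanocyte genes followed the same library: the 10 genes had a median of -0.15 (camera adjusted p = 0.00604, adjusted p = 0.696 with an estimated correlation), which was 0.10 without mutant 2 and did not pass there (camera adjusted p = 0.360). No melanocyte gene was called over all genes or adjusted over the list alone.

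The listed targets of the pathway did not move together. The 22 tested Wnt/beta-catenin target and feedback genes had a median of 0.14, which is 0.05 above that of all genes (camera adjusted p = 0.566), with 6 separate upward and 2 downward. Over all genes 0 were called (4 higher and 1 lower at an unadjusted p under 0.05 with limma), and 2 passed adjusted over the list alone, Twist1 and Dkk2. The dermal transcription factor gene Twist1 was at 3.34 ± 1.02 FPKM in controls and 8.07 ± 1.34 in mutants (adjusted p = 0.0744), and Dkk2, a secreted Wnt inhibitor, at 3.63 ± 1.07 and 8.03 ± 2.03 (adjusted p = 0.105). Wif1 and Wisp1 had log2 differences of 0.56 and 0.48. Wisp2, which was called over all genes, is not in this list. The list's median was 0.04 without control 2, against 0.03 for all genes, and 0.25 without mutant 2, against 0.17. It passed in neither case (camera adjusted p = 0.731 and 0.788). Axin2 (chromosome 11, 108920349 to 108950783), a feedback target in many tissues, was at 7.24 ± 0.81 FPKM in controls and 8.93 ± 0.20 in mutants (log2 difference 0.27, adjusted p = 0.461). Lef1 (chromosome 3, 131110471 to 131224356), a transcription factor partner of beta-catenin that is also strong in hair follicles, was at 17.5 ± 0.54 and 14.1 ± 1.73 FPKM (log2 difference -0.31, adjusted p = 0.464). In both genes the groups did not overlap. The 28 Wnt ligands and receptors had a median of 0.05, below that of all genes, and did not pass (test downward, camera adjusted p = 0.345), with 0 called over all genes and 0 adjusted over the list alone.

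**Figure D3:**
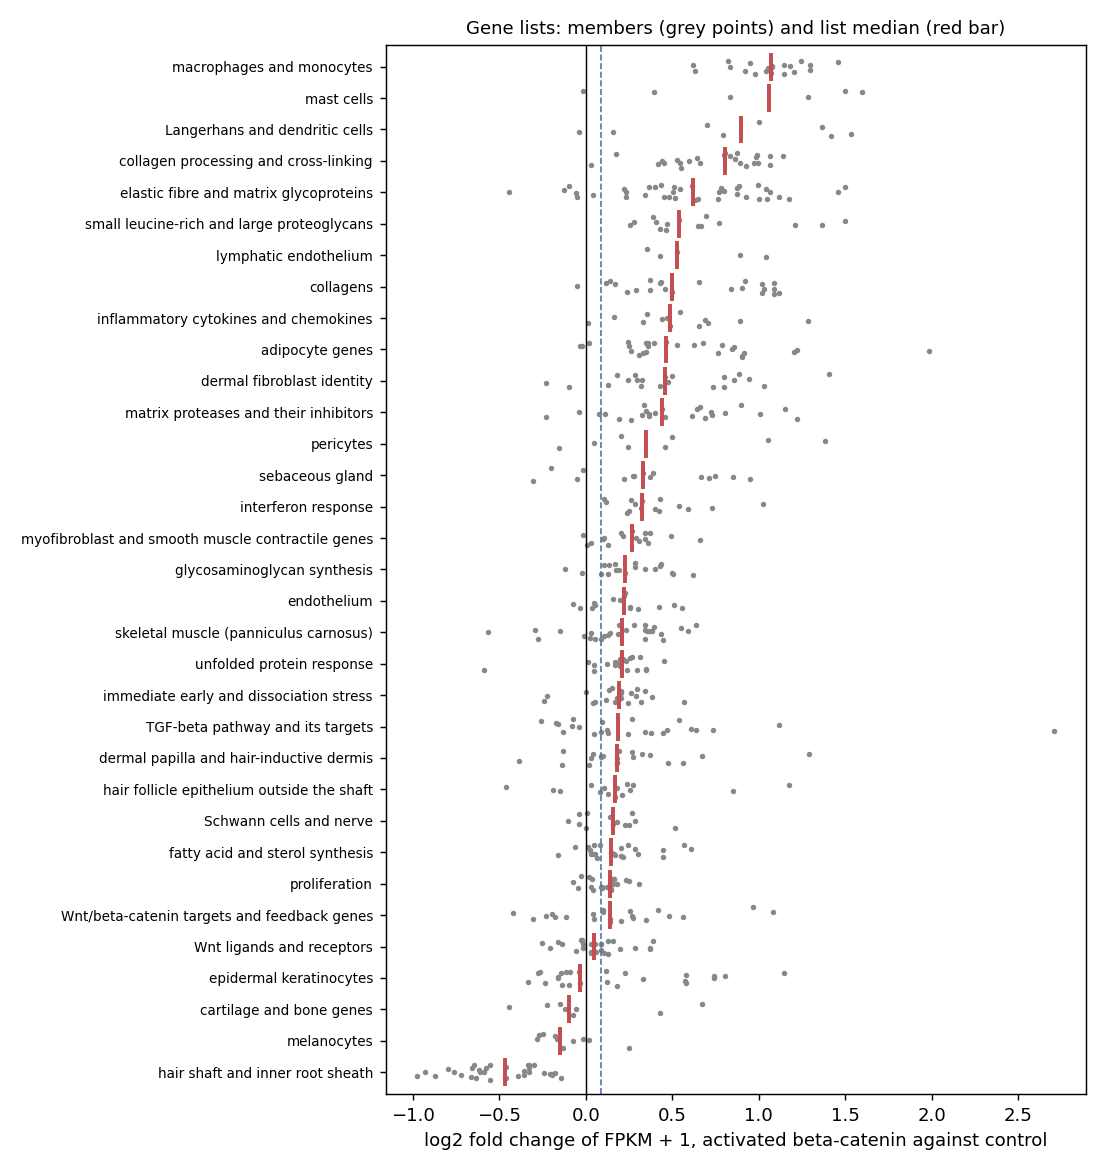
Log2 difference of FPKM + 1 between activated beta-catenin and control dermis for the tested members (grey points) of 33 gene lists fixed beforehand, with each list's median (red bar); the black line marks 0 and the dashed line the median of all tested genes, 0.09. The macrophage list has the highest median, 1.07, and the hair shaft list the lowest, -0.47.

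Of the other lists, glycosaminoglycan synthesis (19 genes, median 0.23, camera adjusted p = 0.0136, adjusted p = 0.722 with an estimated correlation) and sebaceous gland (15 genes, median 0.33, camera adjusted p = 0.0427, adjusted p = 0.696 with an estimated correlation) passed. Neither had a called member, over all genes or adjusted over the list alone. Without mutant 2 their camera adjusted p was 0.192 and 0.223. The glycosaminoglycan list also missed the threshold with library sex as a covariate (0.446) and without both Xist-high controls (0.429). The sebaceous list did so without control 3 (0.288), without mutant 1 (0.0670), without X and Y genes (0.155), with the mean FPKM 5 filter (0.215) and with voom (0.0645). It also did so after median-of-ratios (0.0752), quantile (0.0665) and tissue-gene-free scaling (0.0618). The remaining lists did not pass. They were the unfolded protein response (20 genes, median 0.21, camera adjusted p = 0.121), fatty acid and sterol synthesis (25 genes, 0.15, adjusted p = 0.140), cartilage and bone (8 genes, -0.10, with a mean of 0.004, adjusted p = 0.0952), epidermal keratinocytes (25 genes, -0.03, with a mean of 0.16, adjusted p = 0.262) and stress genes induced by dissociation (23 genes, 0.19, adjusted p = 0.276). The dermal papilla (21 genes, 0.18, adjusted p = 0.288), skeletal muscle (28 genes, 0.21, adjusted p = 0.400), Schwann cell and nerve (13 genes, 0.16, adjusted p = 0.626), follicle epithelium outside the shaft (15 genes, 0.17, adjusted p = 0.626) and proliferation (24 genes, 0.14, adjusted p = 0.760) lists did not pass either. Among these lists 1 gene passed adjusted over the list alone, in the follicle epithelium list. Several of them passed when a library was left out: the cartilage list without control 2 (0.0137) and mutant 2 (0.00397), keratinocytes without control 3 (0.0177), stress genes without control 3 (0.00146), muscle without control 2 (1.42e-08) and mutant 2 (0.00214), and the unfolded protein response without control 3 (0.0482) and mutant 2 (0.0159). With no filter the unfolded protein response (0.00938) and fatty acid (0.00612) lists passed, and the former also after quantile normalization (0.00441) and with voom (0.0472). Muscle passed downward with library sex as a covariate (4.86e-08, median -0.39) and without both Xist-high controls (2.57e-12). It also did so with sample weights (2.51e-17, median -0.50), where the cartilage list passed as well (0.0234). Keratinocytes passed upward and stress genes downward with the sex covariate (0.00190 and 0.00803) and without both Xist-high controls (2.56e-04 and 0.0146). The camera tests of the cartilage, keratinocyte and muscle lists pointed down, although the muscle list's median and mean were above 0. The muscle values spread widely among controls, with list medians of 0.32, -0.92 and 0.62 against the control mean in controls 1 to 3.

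In all, 17 of 33 lists were higher and 2 lower with camera's preset correlation of 0.01, and 0 lists passed with a correlation estimated from these libraries (smallest adjusted p = 0.517) or with fry (smallest adjusted p = 0.208 for one direction). Fry asks whether a list's genes move one way on balance and makes no comparison with other genes. With library sex as a covariate, added after the data were seen, 10 genes rose and 1 fell, of which 4 were among the 18. The median rise of the 18 was 1.35 in that fit against 1.32 in the main one, and the median SE 0.26 against 0.18. In that fit 13 lists were higher and 4 lower. Sample weights, whose estimate did not converge, left 11 lists higher; the adipocyte (camera adjusted p = 0.0925), cytokine (0.118), TGF-beta (0.246), pericyte (0.305), sebaceous (0.305), glycosaminoglycan (0.392) and melanocyte (0.556) lists did not pass there. With only control 3 kept the median rise of the 18 was also 1.35, since the sex covariate likewise leaves the mutants against control 3 alone.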

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

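The voom test, library sex as a covariate, the fit without both Xist-high controls and the fit without X and Y genes were chosen after the data were seen; the others were fixed earlier. All 18 called genes kept a log2 rise above 0 in every alternative that tested them, the lowest at 0.76, but the number called moved in most settings, and the cause was not tested unless given. Against 18 higher and 0 lower, the number higher was 9 with a pseudocount of 0.1 (all 9 among the 18), 10 without the variance trend, 28 after median-of-ratios scaling (17 of the 18 among them), 32 after quantile normalization and 45 after rescaling without muscle, hair, keratinocyte, blood and mitochondrial genes. With no filter 4 were higher out of 21592 tested, 1 of them among the 18. It was 45 with the robust prior, 81 with small RNA genes left out (all 18 among them), 107 at a threshold of 0.1 with 1 lower, and 80 with voom on recovered reads (all 18 among them). Sample weights gave 722 higher and 88 lower, from a weight estimate that did not converge. Library sex as a covariate gave 10 higher and 1 lower, and the fit without both Xist-high controls, in which the lone control is assumed to vary like the mutants, gave 198 and 68. Leaving out 1 library in turn gave 3 (without mutant 2) to 189 (without control 3) higher and 0 to 4 lower. The mean FPKM 5 filter, which tested only 9 of the 18, gave 19 higher with those 9 among them, and leaving out X and Y genes gave 19 with all 18 among them. No pairing by replicate number was seen: deviations of same-numbered libraries correlated at 0.00, 0.04 and -0.08. So few libraries cannot settle whether the numbers mark litters, which the labels do not say. No library correlated best with the library of its own number in the other group. The replicate block gave 67 higher and 1 lower, with a median SE of the 18 of 0.11 against 0.18 in the main fit.

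Of 17 lists higher and 2 lower, 0 and 0 passed with an estimated correlation and 0 and 0 with fry. With an estimated correlation the adjusted p was 0.517 for collagens, proteoglycans, glycoproteins, collagen processing, adipocyte, hair shaft and macrophage genes. With fry it was 0.251 for collagens, glycoproteins, processing and adipocyte genes, 0.226 for proteoglycans, 0.398 for hair shaft and 0.219 for macrophage genes. With camera's preset correlation these 7 lists passed in all other alternatives that enter camera, except the adipocyte list with sample weights (adjusted p = 0.0925). The variance trend and the robust prior do not enter camera, so no list result is given for them. Sample weights left 11 lists higher and 3 lower. The replicate block took the TGF-beta and pericyte lists to 0.0793 and 0.0582 and, among lists that had not passed, contractile genes to 0.0269 and cartilage genes to 0.0395. The mean FPKM 5 filter, which tests fewer members, left 10 lists higher. Lists lower numbered 4 with library sex as a covariate, 4 without both Xist-high controls, and 2 to 4 with 1 library left out.

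Tests of lists that had not passed turned direction in some settings. Skeletal muscle did so with the mean FPKM 5 filter (adjusted p = 0.978), median-of-ratios (0.882), quantile (0.518) and tissue-gene-free scaling (0.529), fry (0.790) and voom (0.827), and ranged from 1.42e-08 to 0.967 with 1 library left out. Without turning, it passed downward with the sex covariate (4.86e-08), without both Xist-high controls (2.57e-12) and with sample weights (2.51e-17). With sample weights the tests turned for contractile (0.920), dermal papilla (0.979), endothelium (0.979), Schwann cell (0.118), proliferation (0.741) and stress genes (0.427). Wnt ligands and receptors turned with no filter (0.572) and fry (0.743), and proliferation with tissue-gene-free scaling (0.811; 0.131 to 0.932 with 1 library left out). Keratinocytes turned with fry (0.743), the sex covariate (0.00190) and without both Xist-high controls (2.56e-04), and ranged from 0.0177 to 0.897 with 1 library left out. Stress genes turned with the sex covariate (0.00803) and without both Xist-high controls (0.0146), and ranged from 0.00146 to 0.925. Under the same 2 settings Schwann cell genes had 0.499 and 0.471 (0.242 to 0.953 with 1 library left out) and the unfolded protein response 0.875 and 0.818. The log2 difference of Hoxb6 ranged from -0.22 to 0.15 with 1 library left out and was above 0 without control 3. Small changes were seldom called in simulation: 10.4% of 1.5-fold changes were, in libraries whose genes were drawn independently, with prior degrees of freedom of 10.5 against 5.44 in the real fit.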

Other observations

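The tests of the other splits of the libraries, of reads from control 1 and of the retinoid genes were set before their results were seen. The tests on library sex, scaling, the share of hair follicle, the hair list without mutant 2 and reads from control 2 were chosen after the results they address were seen.

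Retinoid-handling genes were looked at because Aldh1a1, which makes retinoic acid, and Adh1, an alcohol dehydrogenase that also acts on retinol, were high in all mutants. Aldh1a1 was at 5.85 ± 1.64 FPKM in controls and 22 ± 8.77 in mutants (n = 3 each; log2 difference 1.71, limma adjusted p = 0.0549), and Adh1 at 7.91 ± 2.40 and 21.0 ± 6.35 (1.30, adjusted p = 0.0803). The hypothesis that other genes of retinoid metabolism and signalling rise with them was not borne out. The 16 other tested genes had a median of 0.09, with 11 above 0 and a camera p of 0.512 (p = 0.788 with an estimated correlation). Adh7 was at 0.87 and Stra6, which takes up retinol, at -0.55, with adjusted p of 0.217 and 0.365.

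The 18 called genes were set against chance, sex and scaling. The real split gave 18 called genes, and the highest of the other 9 splits of the 6 libraries gave 2; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Library sex is partly confounded with genotype, since control 3 is the only Y-positive control, and whether it is the cause cannot be told here. With control 3 held out, 189 genes were called higher. On a scale from controls 1 and 2 (0) to the mutants (1), control 3 lay at a median of 0.42 over them (SE 0.04 over genes, which are not independent). These genes were picked for a gap between the mutants and controls 1 and 2. A control left out of that choice tends to lie above 0 even with no effect of sex. In the fit with sex as a covariate 4 of the 18 stayed called. The median rise of all 18 was 1.35 against 1.32 before, and the median SE 0.26 against 0.18. That covariate marks only controls 1 and 2, so the estimates compare the mutants with control 3 alone. The fit of Y-positive libraries alone, control 3 against the mutants, therefore gave the same median rise of 1.35. Both fits rest on 1 control that also took part in choosing the 18. Sex as the whole cause of the 18 is not excluded by them. Library-wide scaling as the whole cause is argued against by median-of-ratios scaling, after which 17 of the 18 were still called. Genotype, sex and litter as causes stay open.

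The list counts are less specific to the genotype split. With camera's preset correlation the real split gave 19 lists past the threshold and another split gave 20; 3 of 10 splits gave as many as the real one. Again 10 splits are too few for a share under 0.05. The split that set controls 1 and 2 with mutant 3 against the rest gave 20, and so did the one of control 1 with mutants 1 and 2. Genes within a list vary together between mice, which camera's preset correlation leaves out. A smaller share of hair follicle RNA alone could raise all dermal lists alike, but the 3 immune cell lists rose by 0.68 log2 more than 7 other non-epithelial cell type lists (SE 0.13 between mice; exact permutation p = 0.1, the smallest possible). The difference was 0.17, 0.00 and -0.12 in controls 1 to 3 and 0.83, 0.52 and 0.75 in mutants 1 to 3. These values argue against a smaller follicle share alone as the source of the immune lists' rise. The lists compared were chosen after their medians were seen, so the size of the gap is no independent test. For the hair list, the median relative to all genes went from -0.55 to -0.31 without mutant 2. That lies at the bound of -0.3 set for the test. The SE of 0.02 is over genes, which vary together, and not between mice. Whether the lower hair RNA is more than that library cannot be told apart with 3 mutants, and a later hair cycle stage or less follicle in the piece of skin taken stay open and untested.

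Mutant 2 had both Xist and Y-linked RNA. Its Xist was 10.6% of the mean of controls 1 and 2, and its 4 Y-linked genes stood at a median of 80.3% (74.0% to 84.1%) of the mean of mutants 1 and 3, or 98.1% after median-of-ratios scaling (90.5% to 102%). Reads from another library could be a source. If control 1 had supplied them, a share of 11.7% would be needed. Of 11120 genes checked, 0 lay significantly below the reads that share would bring (Poisson test, Bonferroni-corrected p under 0.05). The share and the control's reads were taken at the low end of their counting error, so genes slightly below were not counted. For control 2 the share would be 9.77%, and by the same test 1 of 10170 genes, Gm11565, lay below it with 79 reads against 148. Mixing with either control, with a female outside these 6, or Xist expressed by the mouse itself cannot be told apart from these values. The count of called genes without mutant 2 was 3.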
